A study of Mus musculus with 6 samples.

How the data were processed

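RNA sequencing was done on long-term haematopoietic stem cells (LT-HSC), the rare bone marrow cells that can rebuild the whole blood system, from C57BL/6 mice carrying conditional alleles of Prdm16. Per the labels, the cells were sorted as lineage-negative, Sca-1-positive, c-Kit-positive, CD48-negative and CD150-positive. Marrow of 5 mice per genotype was pooled, and the cells were sorted into lysis buffer as 3 technical replicates per genotype. The control group (WT) lacked the Mx1-Cre transgene and the knockout group (KO) carried it. Both groups received 5 injections of pIpC, a double-stranded RNA that switches on the Mx1 promoter. The 3 libraries of a group are therefore portions of 1 pooled sort, and p-values measure the spread between these portions, not between animals.

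The authors deposited 1 table of log2 values for 27179 genes and 6 libraries, identified by NCBI gene ID. Per the submitters' processing notes, FastQC, HISAT2, featureCounts, limma and the mouse build mm10 were used, and versions, strand settings and the handling of multiply mapped reads are not given in the sources used here. The deposited log2 values have the form of log2 CPM, with 0.5 added to the reads and an effective library size as the divisor. Undoing that transform gave whole reads for 100.0% of values within a tolerance of 0.01, the largest distance from a whole number being 0.0011. Library totals recovered in this way ran from 36747729 to 43743795 reads. Totals divided by effective sizes ran from 0.9959 to 1.0042. CPM values given in the text are recovered reads scaled by the same effective size. A gene with 0 reads in every control library was given a floor of 3 reads per library, which is 0.0748 CPM as the mean of the control group. Such floors and all counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

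Gene names and coordinates came from the RefSeq gene table of GRCm38.p6, the assembly that mm10 names, which matched 25275 gene IDs and left 1904 unmatched. No column of values was left unmapped to a sample.

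Genes with at least 1 CPM in at least 3 of the 6 libraries were tested, which left 13018. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with 2 groups of 3 libraries and no block. P-values were adjusted by the Benjamini-Hochberg method, and genes with adjusted p below 0.05 were called. Fold changes are on the scale of these log2 values, which depends on the 0.5-read offset for genes near 0 in 1 group. For those genes levels, reads or bounds are given instead.

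The design, the alternatives and 36 gene lists were fixed before the data were examined. Of the lists, 35 had at least 5 tested members and were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera was repeated with a correlation estimated for each list, and limma's fry gave a directional test of each list. Named genes were Prdm16, the 12 largest changes in each direction and up to 3 members of each list by smallest adjusted p. The 12 were taken among called genes whose 2 groups did not overlap, whose mean log2 value was at or above the median of tested genes (5.21) and whose symbol is not that of a predicted model, clone or pseudogene. Other genes named in the text were chosen after their values were seen, and this is said where they appear.

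Library pairs were compared to look for 1 library deposited more than once. Chi-square per degree of freedom was 42.18 to 58.4 for pairs within a group and 59.74 to 93.1 for pairs between groups, so every pair differed by more than sampling noise. The test was run on simulated counts drawn from the real means and library sizes, in which 200 of 13018 genes were changed. It recovered 13.4% of genes changed 1.5-fold, 35.8% of those changed 2-fold and 71.2% of those changed 4-fold, and called 4 unchanged genes. With no gene changed it called 1 gene and 0 lists. Genes were simulated independently, with variances drawn from limma's fitted prior. The 0 lists therefore do not show how camera behaves where genes of a list are correlated.

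Alternatives were no low-value filter, a filter of 5 CPM, median centring, quantile normalization, no trend, robust eBayes, a replicate block and leaving out each library in turn. Alternatives added after the data were seen were log2(CPM + 0.1), log2(CPM + 1) and log2(CPM + 5), voom in limma on the recovered reads with and without a trend, camera on ranks, and leaving out each library with the genes tested in all 6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.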

Results

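The data comprised 6 RNA-seq libraries of sorted LT-HSC, 3 from control mice and 3 from mice in which Prdm16, a zinc-finger transcriptional regulator, was deleted through Mx1-Cre. Cells were collected 5 weeks after pIpC from mice 8 to 12 weeks old. The control libraries held 40581282, 36747729 and 43743795 reads and the knockout libraries 36810194, 42900113 and 43725862. The first principal component of the tested genes carried 38.4% of the variance and separated the groups, with control scores of -82.7, -52.5 and -15.7 and knockout scores of 74.4, 32.8 and 43.8. The second component (23.3%) set control replicate 1 (68.7) and control replicate 2 (-77) at its ends, with the other libraries from -12.4 to 18.3. Correlations of log2 CPM across genes overlapped, at 0.8826 to 0.9381 for pairs within a group and 0.8358 to 0.9279 for pairs across groups.

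The comparison asks which transcripts of LT-HSC differ when Prdm16 is deleted. Prdm16 itself (gene ID 70673, chromosome 4, 154316122 to 154637360, mm10) had 1630, 1860 and 1381 reads in the control libraries and 323, 388 and 643 in the knockout libraries. Its level was 40.8 ± 9.41 CPM in control and 10.8 ± 3.37 CPM in knockout (SD, n = 3 each), a log2 fold change of -1.93 (SE 0.27, adjusted p = 0.00829). Prdm16 reads were still present in each knockout library, and a gene total does not separate deleted from retained exons. The adjusted p was 0.0967 without the trend and 0.0508 or 0.065 (filter repeated or not) without knockout replicate 2, with log2 fold changes of -1.93 and -1.82.

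Of 13018 genes tested, 53 were higher and 38 lower in knockout (limma, adjusted p below 0.05), and 41 of the higher and 14 of the lower genes changed at least 2-fold. At an unadjusted p under 0.05 there were 1342 genes, a count that includes genes passing by chance. The median gene moved by 0.003 on the log2 scale. Without knockout replicates 1, 2 and 3 in turn, the higher genes numbered 20, 20 and 24, of which 13, 11 and 15 changed at least 2-fold. Without knockout replicate 2 and control replicates 2 and 3 in turn the lower genes numbered 22, 25 and 22. Losses of single calls on leaving out a library are given below over 2 sets of fits, 1 that repeats the filter on the 5 libraries left and 1 that keeps the genes of all 6, and a loss in either set is given. Genes below 1 CPM in every control library, such as Mcpt8 and Ctsg, enter only the second set where a knockout library is left out. Without the trend 33 of 57 called genes that were followed besides Prdm16 lost the call.

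Genes of mature granulocytes gave the 3 largest increases among called genes at or above the median level. S100a8 and S100a9, which encode the subunits of the neutrophil protein calprotectin, rose from 21.2 ± 3.42 to 157.8 ± 40.6 CPM and from 25.1 ± 3.80 to 179.9 ± 37.5 CPM, log2 fold changes of 2.88 (SE 0.20) and 2.83 (SE 0.18). Ngp, a neutrophil granule gene, rose by 2.76 (SE 0.18, adjusted p = 8.2e-05). In the myeloid differentiation list 13 of 29 members rose and none fell, or 18 higher and 1 lower adjusted over the list alone, with a fitted median of 2.47. The neutrophil list had 9 members higher and 1 lower of 19, or 14 and 1 adjusted over the list alone, with a fitted median of 2.78. Both lists were called by camera (adjusted p = 1.2e-14 and 3e-14) and held with an estimated correlation (adjusted p = 0.0196 for each). Of the 19 neutrophil members, 9 are also in another list and 13 had at least 1 CPM in control.

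Other genes of mature blood cells were near or at 0 reads in the control libraries. Prss34 and Mcpt8, proteases of basophils, had 0 reads in each control library and 57.9 ± 10.8 and 16.4 ± 4.66 CPM in knockout, at least 770-fold and 210-fold higher against the floor. Igkc, the kappa light chain constant region, had 0 control reads and 118.3 ± 5.26 CPM in knockout, at least 1500-fold higher. Ctsg, a granule protease, had 2 control reads in all, a ratio of 1350 with a counting interval of 374 to 11200. The following genes were chosen after their values were seen. Epx, the eosinophil peroxidase, had 0 control reads and 101.2 ± 5.15 CPM in knockout. Prg2, eosinophil major basic protein, had 36, 0 and 29 control reads against 13476, 18560 and 15238. Mpo and Elane, enzymes of neutrophil precursors, reached 253.7 ± 18.7 and 66.6 ± 5.54 CPM in knockout from 1.95 ± 1.83 and 0.145 ± 0.252 CPM in control. On leaving out any 1 knockout library the calls of Mcpt8 (adjusted p = 0.0961 to 0.158), Ctsg (0.0596 to 0.0713) and Mpo (0.141 to 0.199) were lost, Mpo also without control replicate 3 (0.0514) and Elane without knockout replicate 2 (0.0573). Without the trend the calls of Mpo (0.32), Elane (0.0834) and Prg2 (0.11) were lost, and that of Mpo also without the filter (0.0835) and with robust eBayes (0.129). In total 7 called genes had 0 reads in every control library and 17 of the higher genes had a control mean below 1 CPM.

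**Figure D1:**
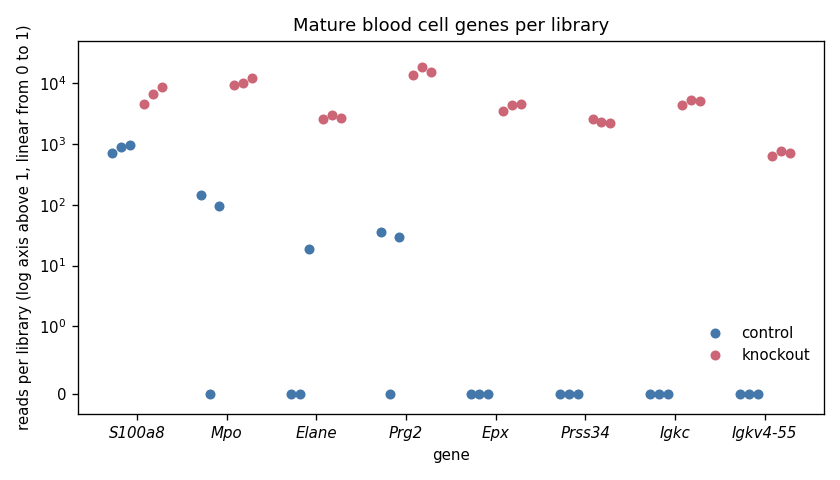
Reads per library for 8 genes of mature blood cells, on a log axis above 1 read and a linear axis from 0 to 1; each point is 1 library, with control in blue and knockout in red. The 3 control libraries of Epx, Prss34, Igkc and Igkv4-55 sit at 0, while the 3 knockout libraries of Epx sit at 3522, 4445 and 4577 reads.

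Lists of further cell types were tested in the same libraries. Camera called 6 of the 7 lists of other cell types higher, namely neutrophil, mast cell and basophil (2 of 11 members called, adjusted p = 2.8e-06), B and plasma cell (1 of 16, 0.00116), stromal (1 of 10, 0.0284), macrophage (0 of 13, 0.0456) and endothelial genes (0 of 16, 0.0466). With an estimated correlation the adjusted p was 0.0552, 0.167, 0.201, 0.201 and 0.229 for the last 5 of these. By ranks the neutrophil (adjusted p = 8.7e-06) and mast cell lists (0.00867) were called, and the B and plasma cell (0.372), stromal (0.164), macrophage (0.182) and endothelial lists (0.163) were not. With a filter of 5 CPM the same 4 were not called (0.163 to 0.246). The T and NK cell list was not called (0 of 7 members, adjusted p = 0.663). Over all lists camera called 16, and 6, 8 and 6 without knockout replicates 1, 2 and 3 in turn. Of the 6 lists of other cell types only the neutrophil list was called in each of these 3 fits, in which genes below 1 CPM in every control library miss the filter. With the genes of all 6 libraries kept, the same fits called 12, 13 and 14 lists. In these the macrophage and endothelial lists were not called without knockout replicate 1 (adjusted p = 0.277 and 0.273) or 2 (0.0908 each), nor the stromal list without knockout replicate 2 (0.0675). Without control replicate 1 the stromal and endothelial lists were not called (adjusted p = 0.134 and 0.0769 with the filter repeated). The macrophage list was also not called after quantile normalization (adjusted p = 0.0982), with log2(CPM + 1) or log2(CPM + 5) (0.0547 and 0.0706) or with replicate number as a block (0.09). Cxcl12, a stromal chemokine, was 1.11 ± 0.766 CPM in control and 11.6 ± 4.12 in knockout, and its call was lost on leaving out control replicate 3 (adjusted p = 0.0952) or any 1 knockout library (0.163 to 0.233), and also without the trend (0.201), without the filter (0.0869) and with voom (0.116).

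Lists of blood lineages were called higher as well. Among megakaryocyte and platelet genes 4 of 25 rose and 1 fell (adjusted p = 0.00282). Slc14a1, a urea transporter, rose by 0.88 (SE 0.08) and Plek, a platelet signalling protein, by 0.70 (SE 0.09), while Thbs1, a platelet and matrix glycoprotein, fell by 1.56 (SE 0.16, adjusted p = 0.00115). Among multipotent progenitor genes 5 of 20 rose (adjusted p = 0.00282), Plac8 by 1.02 (SE 0.12) and Lgals1 by 1.36 (SE 0.21), the latter call being lost without control replicate 3 or any 1 knockout library (adjusted p = 0.0538 to 0.101). Another of the 5 was Ctsg, the granule protease given above. Of the 20 members 13 are also in another list, as are 8 of 17 lymphoid, 5 of 25 megakaryocyte and 0 of 22 erythroid members. One lymphoid gene, Cd52, rose of 17 (adjusted p = 0.0063 for the list), and its call was lost without control replicate 3, knockout replicate 2 or knockout replicate 3 (0.0514 to 0.136). In the erythroid list (0 higher and 1 lower of 22, adjusted p = 9e-04) Car2, carbonic anhydrase 2, fell by 0.47 (SE 0.04), while Hbb-bs, a globin gene, was at 0.240 ± 0.156 CPM in control and 3.85 ± 1.42 in knockout without passing the test (adjusted p = 0.129). With an estimated correlation the adjusted p of these 4 lists was 0.111, 0.111, 0.201 and 0.246. By ranks the multipotent progenitor and lymphoid lists were not called (adjusted p = 0.112 and 0.332). On leaving out any 1 knockout library with the filter repeated, the multipotent progenitor (0.0682 to 0.201), lymphoid (0.384 to 0.909) and erythroid lists (0.0797 to 0.299) were not called, and with the genes of all 6 kept they were. With a filter of 5 CPM the erythroid and lymphoid lists were not called (adjusted p = 0.209 and 0.946), nor was the lymphoid list with voom (0.0873). Without the trend the calls of Slc14a1 (adjusted p = 0.0512), Plek (0.099), Plac8 (0.0934), Lgals1 (0.0947) and Car2 (0.212) were lost. The neutrophil markers S100a8, S100a9 and Ngp were higher in the same 3 libraries.

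Immediate early genes, which respond within minutes to stimulation or stress, were lower in knockout. Of 23 tested members of the list 9 fell and 1 rose, or 13 lower and 1 higher adjusted over the list alone, with a median of -0.49 (camera adjusted p = 3e-09, and adjusted p = 0.0552 with an estimated correlation). Fos fell from 757 ± 79.0 to 348.2 ± 18.5 CPM and Jun, its partner in the AP-1 factor, from 896.2 ± 67.6 to 464.3 ± 24.9 CPM, log2 fold changes of -1.12 (SE 0.08) and -0.95 (SE 0.07), both with adjusted p = 0.00017. Egr1, a zinc-finger transcription factor, fell by 1.26 (SE 0.10), Zfp36, a protein that destabilizes mRNA, by 0.98 (SE 0.10) and Dusp1, a MAP kinase phosphatase, by 0.90 (SE 0.08). The other members that fell were Fosb, Junb, Ier2 and Klf6, and the member that rose was Hspa8, a constitutive heat shock protein, with a log2 fold change of 0.39 (SE 0.05). These 5 were named after their values were seen, and the Klf6 call was lost on leaving out any 1 library except control replicate 3 (adjusted p = 0.0806 to 0.154). Those of Junb (0.0518) and Hspa8 (0.0509) were lost without knockout replicate 3. Without the trend the calls of Junb (0.0965), Ier2 (0.136), Klf6 (0.263) and Hspa8 (0.294) were lost. The neutrophil list was higher in the same libraries (median 2.78).

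**Figure D2:**
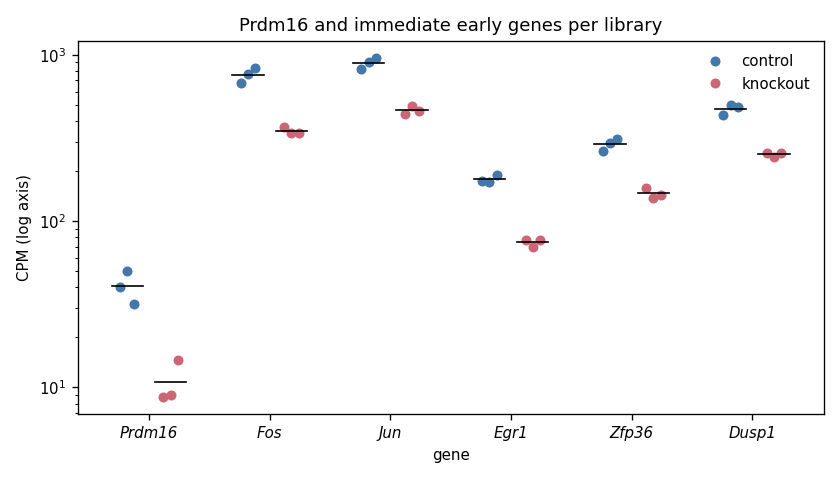
CPM per library on a log axis for Prdm16 and 5 immediate early genes; each point is 1 library (control in blue, knockout in red, n = 3 each) and each line a group mean. The knockout points lie below the control points for each of these genes, with Fos means of 757 and 348.2 CPM.

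Interferon-stimulated genes were called higher as a list (camera adjusted p = 8.5e-09, and adjusted p = 0.0552 with an estimated correlation). Of 30 members 2 rose, or 8 adjusted over the list alone, and the median was 0.34. Irf7, a transcription factor of the interferon response, rose by 0.74 (SE 0.13, adjusted p = 0.0368), a call lost on leaving out any 1 library (0.0782 to 0.177), and Ifi27l2a by 2.85 (SE 0.51, adjusted p = 0.0393), lost on leaving out any 1 library except control replicate 3 (0.0723 to 0.224). Without the trend both calls were lost (0.054 and 0.203). Ifit3 was at 3.38 ± 1.28 CPM in control with a log2 fold change of 1.76 (SE 0.38) that did not pass the test (adjusted p = 0.0869). The mature blood cell genes above were higher in the same libraries. In the opposite direction, Gbp6, a guanylate-binding protein induced by interferon (chromosome 5, 105270702 to 105295871), fell by 1.24 (SE 0.18, adjusted p = 0.0101). Its call was lost without control replicate 3 or knockout replicates 1 or 2 (0.0505 to 0.0685) and without the trend (0.108), and reads shared with neighbouring Gbp copies cannot be separated in the deposited values.

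Genes beside Gbp6 were examined after its value was seen. All 7 tested genes from Abcg3, an ABC transporter, to Gbp11 (chromosome 5, 104935057 to 105346476) had lower values in knockout, with a median log2 fold change of -1.36, and 3 of them passed the test. Gbp4 (-1.91, SE 0.29, adjusted p = 0.0139), Gbp6 and Abcg3 (-0.85, SE 0.16, adjusted p = 0.0466) were called. Gbp8 (-1.36, adjusted p = 0.129), Gbp9 (-1.58, 0.0776), Gbp10 (-2.54, 0.352) and Gbp11 (-0.75, 0.452) were not. The Abcg3 call was lost on leaving out any 1 library (adjusted p = 0.0514 to 0.206), and the Gbp4 call without knockout replicate 2 (0.0554). Without the trend neither was called (0.209 for Abcg3 and 0.189 for Gbp4). The flanking genes Zfp951 (0.31, SE 0.58), Lrrc8b (-0.02, SE 0.18), Lrrc8c (-0.54, SE 0.14, adjusted p = 0.194) and Lrrc8d (-0.30, SE 0.11, 0.402) were not called, nor were the Gbp genes of chromosome 3, Gbp2 (-0.17), Gbp3 (-0.17), Gbp5 (0.16) and Gbp7 (0.21).

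**Figure D3:**
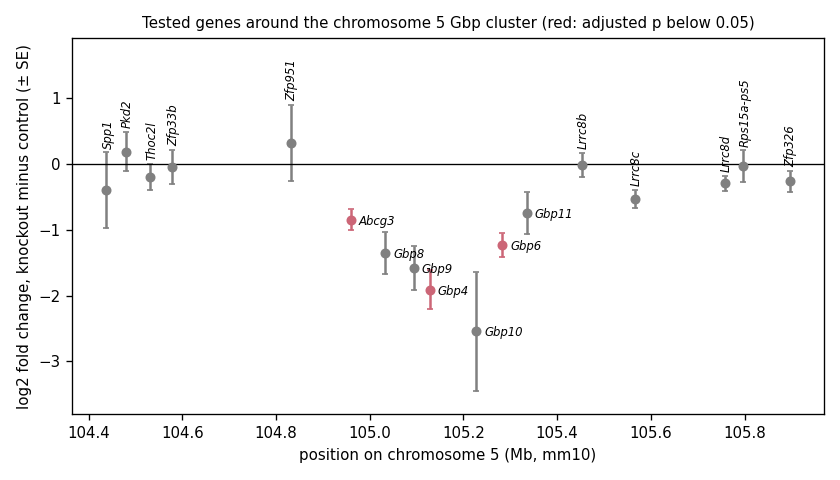
Log2 fold change, knockout minus control, with its SE for each tested gene against position on chromosome 5 (Mb, mm10); red points have adjusted p below 0.05 and grey points do not. The 7 genes from Abcg3 to Gbp11 lie below 0, between -0.75 and -2.54.

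Genes that mark LT-HSC were not called as a list (adjusted p = 0.443, median 0.05). Of 30 members 2 fell, or 4 lower and 3 higher adjusted over the list alone. Angpt1, the ligand of the Tie2 receptor, fell by 0.34 (SE 0.06, adjusted p = 0.0341) and Sult1a1, a sulfotransferase, by 1.21 (SE 0.22, adjusted p = 0.0441). The Angpt1 call was lost on leaving out any 1 library (adjusted p = 0.0567 to 0.158), and so was the Sult1a1 call (0.0573 to 0.178), except without knockout replicate 2 where the filter was repeated. Without the trend both were lost (0.408 and 0.201). Quiescence regulators were called lower (2 of 25 fell, median -0.06, adjusted p = 0.0447, and adjusted p = 0.201 with an estimated correlation). That list was not called on leaving out control replicate 1 or any 1 knockout library (adjusted p = 0.0732 to 0.154), by ranks (0.163), with a filter of 5 CPM (0.0581) or with replicate number as a block (0.0887). The 2 that fell were Egr1, also an immediate early gene, and Txnip, a regulator of glucose uptake and redox state, by 0.54 (SE 0.08), with adjusted p = 0.0514 without control replicate 3 and 0.282 without the trend. The neutrophil list rose in these libraries too (median 2.78).

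Of the lists of growth, MYC targets and ribosome biogenesis genes were called higher (0 of 30 called, 27 with a positive value, median 0.12, adjusted p = 0.001) and cytosolic ribosomal proteins lower (0 of 30 called, 2 positive, median -0.08, adjusted p = 0.0376). With an estimated correlation the adjusted p was 0.221 and 0.721, and after quantile normalization the ribosomal protein list was not called (adjusted p = 0.189). Nor was it without control replicates 1 or 2 or knockout replicates 1 or 3 (adjusted p = 0.0627 to 0.646), with a filter of 5 CPM (0.0606), with a replicate block (0.0554) or with log2(CPM + 1) (0.0531). Hspa5, the endoplasmic reticulum chaperone BiP, rose by 0.36 (SE 0.05, adjusted p = 0.00776) in an unfolded protein response list that was not called (1 of 23, adjusted p = 0.198). The Hspa5 call was lost without control replicate 2 (0.0526), without knockout replicate 3 (0.0586) and without the trend (0.345). The neutrophil list was higher in the same libraries (9 of 19 members called higher and 1 lower, median 2.78).

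**Figure D4:**
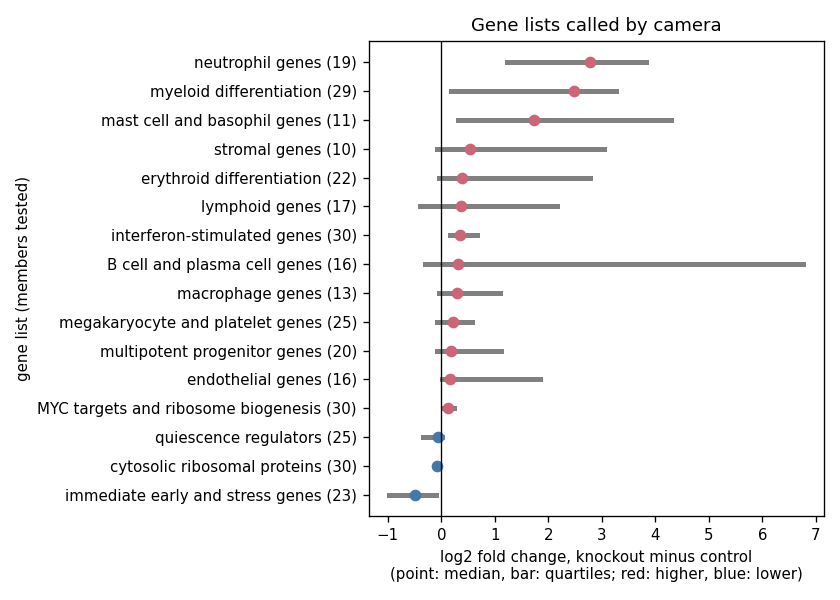
Median (point) and quartiles (bar) of the fitted log2 fold changes, knockout minus control, for the 16 lists called by camera; the number of tested members is in parentheses, red marks lists called higher and blue lists called lower. The neutrophil list sits at 2.78 and the immediate early list at -0.49.

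The remaining lists were not called by camera. DNA replication (adjusted p = 0.209), mitosis (0.246), p53 targets (0.739), apoptosis (0.794), NF-kB signalling (0.516), HOXA and MLL-associated genes (0.812), TGF-beta signalling (0.461), antioxidant genes (0.324), oxidative phosphorylation (0.715), glycolysis (0.663), mitochondrially encoded genes (0.406), cholesterol synthesis (0.151) and histones (0.0764) had 0 called members. The same held for the PRDM family and its partners (0.245), in which Mecom, a close relative of Prdm16, was at 146.5 ± 7.38 CPM in control and 198.2 ± 22.0 in knockout (adjusted p = 0.141). Mitochondrial dynamics (0.179) held 1 lower member, Prdm16, and adhesion genes (0.144) held 1 higher member, the integrin Itgb2, which rose by 0.98 (SE 0.15), a call lost without control replicate 2 or any 1 knockout library (adjusted p = 0.0549 to 0.114) and without the trend (0.173). For apoptosis, NF-kB and HOXA genes the median, the mean and the test did not share a sign. Of the sex-linked list only Xist and Tsix were tested, and neither was called.

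The remaining genes of the rule were called without belonging to these groups. Higher in knockout were Slfn2 (log2 fold change 1.49), a regulator of immune cell quiescence, the protease inhibitor gene Serpina3g (0.74), the lipid transporter gene Mfsd2b (0.64) and the dynein light chain gene Dynll1 (0.62). Lower were Pygm, muscle glycogen phosphorylase (-1.15), the myosin light chain gene Myl10 (-1.15), Pcp4l1 (-0.92), the transcription factor Sox6 (-0.90) and the ETS factor Etv5 (-0.88). The calls of Serpina3g, Pygm and Myl10 held on leaving out each library in turn. Those of the others were lost in some of these fits, namely Slfn2 on leaving out any 1 knockout library (adjusted p = 0.0537 to 0.109), Dynll1 on leaving out any 1 library except control replicate 1 (0.0501 to 0.0782) and Mfsd2b on leaving out any 1 library (0.0523 to 0.164). Likewise Pcp4l1 was lost on leaving out any 1 library except knockout replicate 1 (adjusted p = 0.0524 to 0.0873), Sox6 without control replicate 2 or knockout replicates 1 or 3 (0.0546 to 0.0716) and Etv5 on leaving out any 1 library except knockout replicate 1 (0.0676 to 0.2). Without the trend each of these 9 genes except Myl10 lost its call (0.0512 to 0.21). With replicate number as a block the calls of Gbp4, Abcg3, Klf6, Irf7, Ifi27l2a, Itgb2, Angpt1, Sult1a1, Cd52, Cxcl12, Mfsd2b and Etv5 were lost (adjusted p = 0.0506 to 0.145). Without the filter those of Abcg3, Klf6, Ifi27l2a, Angpt1, Sult1a1, Cxcl12, Mpo and Etv5 were lost (adjusted p = 0.0501 to 0.0869).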

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

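The alternatives that are not among those fixed before the data were examined are the offsets on CPM, voom, camera on ranks and the repeat of the leave-one-out fits on the genes of all 6 libraries; they were chosen after seeing the data. The planned edgeR and DESeq2 fits were not run because the deposited unit is log2, although whole reads could be recovered from it. The planned pseudocounts do not apply to log2 values, and the offsets named here were put on recovered CPM. Main counts were 53 higher and 38 lower genes, 41 and 14 of at least 2-fold, and 16 gene lists. The higher counts rose to 83 and 71 without the low-value filter, to 105 and 86 with log2(CPM + 1) and to 104 and 64 with log2(CPM + 5), and the lower count rose to 59 and 64 with these 2 offsets. Without the trend 15 genes were lower, and Prdm16 kept -1.93 with adjusted p = 0.0967. Over all settings run, the adjusted p of Prdm16 lay between 0.00247 and 0.0967. Leaving out 1 library gave 20 to 66 higher, 19 to 31 lower, 11 to 55 higher at least 2-fold and 9 to 16 lower at least 2-fold genes, 6 to 16 lists and Prdm16 values of -2.17 to -1.76. Without a knockout library only 75 of the 91 called genes could be tested, since genes below 1 CPM in every control library then miss the 3-library minimum. With the genes of all 6 libraries kept, 12 to 16 lists were called and the higher genes numbered 20 to 64, over knockout and control libraries left out. Without knockout replicates 1, 2 and 3 in turn, 52, 41 and 43 genes were then called. With the filter repeated these were 46, 42 and 53, so that filter alone does not account for the fall from 91 called genes. Lists numbered 8 with the stricter filter, 9 with camera on ranks and 2 with an estimated correlation. Fry called 17 lists, among them 15 of the 16 camera lists in the same direction. By fry the ribosomal protein list was not called (adjusted p = 0.467), while the PRDM family (0.0351) and unfolded protein response lists (0.0328) were called higher. The trend settings do not enter camera. With the replicate number as a block 23 genes were lower. Same-numbered libraries had correlations of deviations of -0.01, -0.021 and 0.02, so the numbers give no sign of pairing. The causes of the other changes were not tested. Voom on the recovered reads called 61 higher and 52 lower genes, or 54 and 43 with a trend. All 91 called genes kept their direction under every setting in which they were tested, and no named gene reversed. For the called genes this was largely fixed beforehand. Their 2 groups did not overlap, so leaving out a library could not reverse them, and filters, trend and robust eBayes do not change fold changes. Of 57 called genes followed under each setting besides Prdm16, 33 lost the call without the trend and 29 in at least 1 fit that left out a library. Depth limits the genes near 0 in control to bounds.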

Other observations

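The tests of the blood cell pattern by lists, V genes and the upper quartile of CVs, of stem cell expression, of immediate early genes, of interferon and of shared reads were chosen after the results were seen, and so were the patterns. In the immunoglobulin genes, looked at after their values were seen, the knockout libraries shared 1 leading kappa and 1 leading heavy V gene. Reads fell on 15, 22 and 17 kappa and 11, 26 and 20 heavy V genes in knockout replicates 1, 2 and 3. Igkv4-55 had 625, 780 and 719 reads, 70.8%, 72.0% and 76.5% of all kappa V gene reads, and Ighv2-9 had 242, 285 and 265 reads, 78.8%, 66.9% and 57.4% of heavy V gene reads. Both were at 0 in each control library. By group means alone, 21 genes had under 0.5 CPM in control and at least 5 CPM in knockout, and 0 genes showed the opposite.

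The first pattern is that blood cell genes near 0 in control were present in knockout. Different stray cells with unrelated V genes would give each library its own leading V genes. Igkv4-55 and Ighv2-9 instead led in all 3 knockout libraries, with a lowest share of 57.4%. For the immunoglobulin genes this argues against such cells. Since the 3 libraries came from 1 pool, different stray cells that shared these V genes cannot be excluded. For the other 17 genes, a few stray cells per library would make reads uneven, but the upper quartile of their CV over the knockout libraries was 28.4%, below the 90th percentile of 44.6% in genes at similar level. Of the 17, 16 lay below it and Mmp8 (78.1%) did not. Many stray cells per library would be as even, and for these 17 cannot be told apart from a source shared by the libraries. The median CV of all 21 was 17.7%, against 17.0% in genes at similar level, so the bound set beforehand, a median no higher than that, was not met. For these 17, RNA or cells of other marrow types in the knockout pool cannot be told apart from expression by the knockout stem cells with 1 pool per genotype. Stem cells have not rearranged or class-switched immunoglobulin genes, but a leading V gene alone cannot decide against expression by them. In control replicates 2 and 3, Igkv2-137 had 38 of 51 and 55 of 56 kappa V gene reads, with 0 Igkc reads. Stem cell expression would not raise Igha, the IgA constant region (named after its values were seen). It had 0, 0 and 8 control reads against 2465, 3509 and 3301 in knockout. The Igha values argue against stem cell expression for that gene, though gene totals do not show which segments are joined. For the V genes the source is left open. With the 21 genes and all called genes taken out, 1 of the 7 lists of other cell types was called higher, the neutrophil list (8 members, adjusted p = 0.0331), and either source could give this. Taking out called genes by itself makes a call less likely. The mast cell, macrophage, endothelial, stromal and B and plasma cell lists leaned higher without a call (camera adjusted p = 0.0739 to 0.366), and the T and NK cell list lower (0.663). Among the most abundant of the 21 in knockout were Igkc at 118.3 CPM and Epx at 101.2. Prg2 (381.9 CPM) and Mpo (253.7) were higher but not among the 21, with control means of 0.519 and 1.95 CPM. The cells were sorted as lineage-negative and CD48-negative, but whether these gates removed all cells or RNA carrying such transcripts was not tested.

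The second pattern is that immediate early genes were lower in knockout, with a list median of -0.49. Dilution of stem cell RNA by other cells would lower LT-HSC genes alike, but their median was 0.05 with a lower quartile of -0.12, which argues against it. A difference in handling or sorting between the 2 pools could also change these genes, and cannot be told apart from genotype with 1 sort each. Heat shock genes did not fall together, with a median of 0.05 over 5 genes from -0.14 for Hspa1a to 0.70 for Hsph1. An effect of Prdm16 deletion remains among the open explanations. Since only the knockout group carried Mx1-Cre, the transgene itself cannot be told apart from the deletion, here or in the other patterns.

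The third pattern is the lower run of Abcg3 and Gbp genes on chromosome 5. In random gene orders a window of 7 neighbours with as low a mean moderated t (-4.73) arose in 3 of 10000 permutations (permutation p = 4e-04), with the window length chosen from the run itself and Gbp copies not independent. A general fall of interferon signalling is argued against by the interferon-stimulated median of 0.34, whose lower quartile was 0.17. That list does not separate kinds of interferon, and the mature blood cell genes higher in the same libraries could also move its median. The Gbp genes of chromosome 3 ran from -0.17 for Gbp2 and Gbp3 to 0.21 for Gbp7, and none was called. Shared reads between Gbp copies could spread 1 change over the 6 Gbp genes, of which 2 were called, and cannot be told apart from separate changes without the reads, but they would not lower Abcg3 (-0.85), whose call is lost on leaving out any 1 library. A sequence difference linked to this interval was not tested.

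There are 10 ways to split the 6 libraries into 3 and 3, too few for a share under 0.05. This comparison was also chosen after the results were seen. Every other split mixes knockout and control libraries, so a real group difference would add to its spread and reduce its calls. The real split gave 53 higher, 38 lower, 41 higher at least 2-fold and 14 lower at least 2-fold genes, and the highest of the others gave 0 of each, so that 1 of the 10 splits reached the real counts. At an unadjusted p under 0.05 limma gave 1342 genes for the real split and 372 to 758 for the others. The real split gave 16 lists and the highest other 4, so that 1 of 10 splits gave as many lists.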
